A study of Mus musculus with 12 samples.

How the data were processed

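Transcript levels were measured in uteri of adult ovariectomized mice on 12 single-colour Agilent arrays, with 1 mouse per array. Per the labels, the mice were at least 10 weeks old, of mixed C57bl6/J and 129 background, and were left for 10 to 14 days after ovariectomy. Each received 100 ul of saline or of estradiol (E2, dose not stated) and the uterus was taken 2 h later. Wild-type (WT) mice were set beside EAAE mice, which per the series title carry a DNA binding deficient estrogen receptor alpha, the product of Esr1. Each of the 4 groups (WT saline, WT E2, EAAE saline, EAAE E2) held 3 mice. Per the labels, Cy3-labelled cRNA was made from 500 ng of total RNA of each uterus.

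Per the file headers, the authors scanned the arrays and extracted spot intensities with Agilent Feature Extraction 9.5.3.1 (9.5 in the submitters' processing notes). The deposited processed signal is a linear intensity that was corrected for background and for spatial trends within each array, per the file headers, and not scaled between arrays. The deposited table of the whole series held the same intensity values on all 45018 spots of every array, with column medians of 147.7 to 225.4, so it was uncentred, linear and of the same direction. Each array carried 1639 control spots, which were left out, and 43379 others. Median processed intensity per array was 162.5 to 249.5, the 75th percentile 1324.4 to 1851.8 and the median local background 62.0 to 81.0. Between 63.39 and 73.6% of the probes were well above background. From 1 to 16 spots per array were marked as outliers and left out, and 3 to 5 were saturated and kept. Arrays give no counts, so the number of mice limits the precision.

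The unit of all changes given here is log2. The deposited intensity of each spot was taken to log2, the 75th percentile of its array was subtracted, and spots of the same probe were averaged. Of 41174 probes, 29017 were well above background on all arrays of at least 1 group and 12157 were removed. For the 6729 genes with several tested probes, the probe with the highest mean over all 12 arrays stood for the gene, which left 19304 genes (153 of them known by probe only). Where other probes of a named gene disagreed, their values are given. Names came from the systematic accession for 22951 probes, another accession for 124, the symbol for 6582 and a synonym for 3077, matched to a RefSeq table of assembly GRCm38.p6 that served for names only. The name in the files was kept for 8155 probes and 285 had none. Coordinates are those of the files (mm7). Where all arrays of the dimmer group were not well above background, a bound is given as "at least N-fold": the mean of the brighter group against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value of any probe well above background (-6.14 to -5.14 on the log2 scale). Such genes have no measured fold, and their log2 differences are fitted values.

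Differences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) over all 12 arrays, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were E2 against saline in WT, E2 against saline in EAAE, the difference between these responses (EAAE minus WT), EAAE against WT in saline, and EAAE against WT after E2. Per-array means of gene sets were compared with an exact permutation test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots. Lists of 35 pathways, responses and cell types, written from general knowledge, were tested with limma's camera in 4 of the comparisons. Its preset correlation between genes was 0.01, with an estimated correlation as an alternative, and its p was adjusted over the 35 lists of each comparison. Members of a list past the threshold were counted over all genes and adjusted over the list alone. Some genes stand in several lists, so the lists are not independent. Known estrogen targets share Fos, Egr1, Myc and Cebpb, among others, with immediate early genes. They share Vegfa and Adm, among others, with vascular genes, and Errfi1 and Sgk1 with glucocorticoid-inducible genes. The alternatives run on lists were the estimated correlation, quantile scaling, slide as a block, slide with position, the replicate block and leaving out each array, and ranges of a list's adjusted p cover these without the estimated correlation. Camera sets a list against the other genes, so its direction can differ from the sign of the list's median or mean.

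Named genes were Esr1, the 12 largest rises and 12 largest falls of each comparison and, in each list, up to 4 members with the smallest p. Fos, Myc, Egr1, Igf1, Pgr, Greb1, Cdkn1a, Vegfa, Wnt4, Ltf, Lif, Ramp3, Hspa5, Ccnd1, Cebpb and Txnip were added in every comparison. The largest changes had to pass the threshold, carry a gene symbol, be well above background on all arrays of the higher group and, except for the response difference, have groups that did not overlap. Not all members are printed. The groups, comparisons, tests, lists, the naming rule and the alternatives were fixed before the data were examined. The alternatives chosen then were normexp background correction (offset 50), quantile or array median scaling, no filter or a filter on all 12 arrays, slide as a block, replicate number as a block, only the groups compared, all probes of a gene, a trended robust variance, the deposited series table, a 2-fold threshold and leaving out each array in turn. Position on the slide as a linear term, alone and with the slide block, was added after the data were seen. Lif and the list members Dusp5, Irs2, Dlx6, Hspa1b, Zbtb16, Xaf1, Igkc, Trbc1, Hbb-b1, Hbb-bs, Ahsp and Zp1 were not analysed here.

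The arrays lay on 3 slides of 4 and every slide held more than 1 group, so each result was also fitted with slide as a block and computed within slides. The EAAE E2 arrays all lay at position 4 of their slide, which no other group used. The WT saline arrays lay at positions 1, 1 and 2 of slides 1, 3 and 3. The EAAE saline arrays lay at positions 2, 3 and 3 of slides 2, 1 and 2. Only slide 1 held both of these groups, so genotype under saline is partly tied to slide and position. The fits were tested on simulated data with 50 changed genes per size. At log2 changes of 0.5, 1, 2 and 3, calls were made for 28, 84, 94 and 100% of changed genes in WT, for 22, 72, 94 and 98% in EAAE, and for 6, 48, 88 and 92% for the response difference. In the real data 49.4% of genes were called in WT and 37.5% for the response difference, far more than were changed here. The adjusted threshold depends on that share, so these recovery rates need not hold there. Among the simulated calls, 4.42, 2.42 and 6.98% were false. A list shifted by 0.5 was the only 1 of the 35 called in each of these simulations. Simulated genes varied independently, so this does not cover false list calls among genes that vary together.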

Results

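The data are whole-uterus transcript profiles of 12 ovariectomized mice in 4 groups of 3: WT saline, WT E2, EAAE saline and EAAE E2. The labels number the mice of each group from 1 to 3, and these numbers name the arrays here. Estradiol acts in the uterus mainly through estrogen receptor alpha, which binds estrogen response elements in DNA directly or reaches genes through other factors. The comparisons ask which early transcript changes, at 2 h, need direct DNA binding by this receptor, and how the uterus that lacks this activity differs before hormone is given. Over all tested probes, arrays of 1 group correlated with r of 0.9825 to 0.9935 (12 pairs), and arrays of different groups with r of 0.9184 to 0.9883 (54 pairs). The first principal component carried 59.9% of the variance, the second 16.9% and the third 5.2%.

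Esr1 transcript was well above background on every array. The series title describes a change in DNA binding and no loss of the gene, so its level can check the labels only in part. Its brighter probe (chromosome 10, 5343241 to 5343300, mm7) lay at log2 2.96 ± 0.10 relative to the array's 75th percentile (SD, n = 3) in WT saline and 2.71 ± 0.05 in WT E2. It lay at 3.35 ± 0.12 in EAAE saline and 3.13 ± 0.12 in EAAE E2. Esr1 was 0.40 higher in EAAE than in WT under saline (adjusted p = 0.0101), a call that was lost with slide as a block (0.413, adjusted p = 0.0521) and with position (0.347, adjusted p = 0.106). E2 lowered it by 0.25 in WT (SE 0.09, adjusted p = 0.0499), and moved it by -0.22 in EAAE (adjusted p = 0.277). The WT call was lost without WT saline 2 (adjusted p = 0.141), WT saline 3 (0.133), WT E2 1 (0.0983), WT E2 2 (0.142) or WT E2 3 (0.0737). It was also lost without EAAE saline 2 (0.0573), EAAE saline 3 (0.0563) or EAAE E2 2 (0.0617), and with the array median (0.427). The responses did not differ (0.02, adjusted p = 0.902). A dimmer probe (5345231 to 5345290) gave 0.14 for E2 in WT and -0.30 for genotype under saline, so the probes disagreed in sign. After E2 they disagreed on genotype with both past the threshold, at 0.42 (adjusted p = 0.00323 over all probes) and -0.49 (adjusted p = 0.0111).

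**Figure D1:**
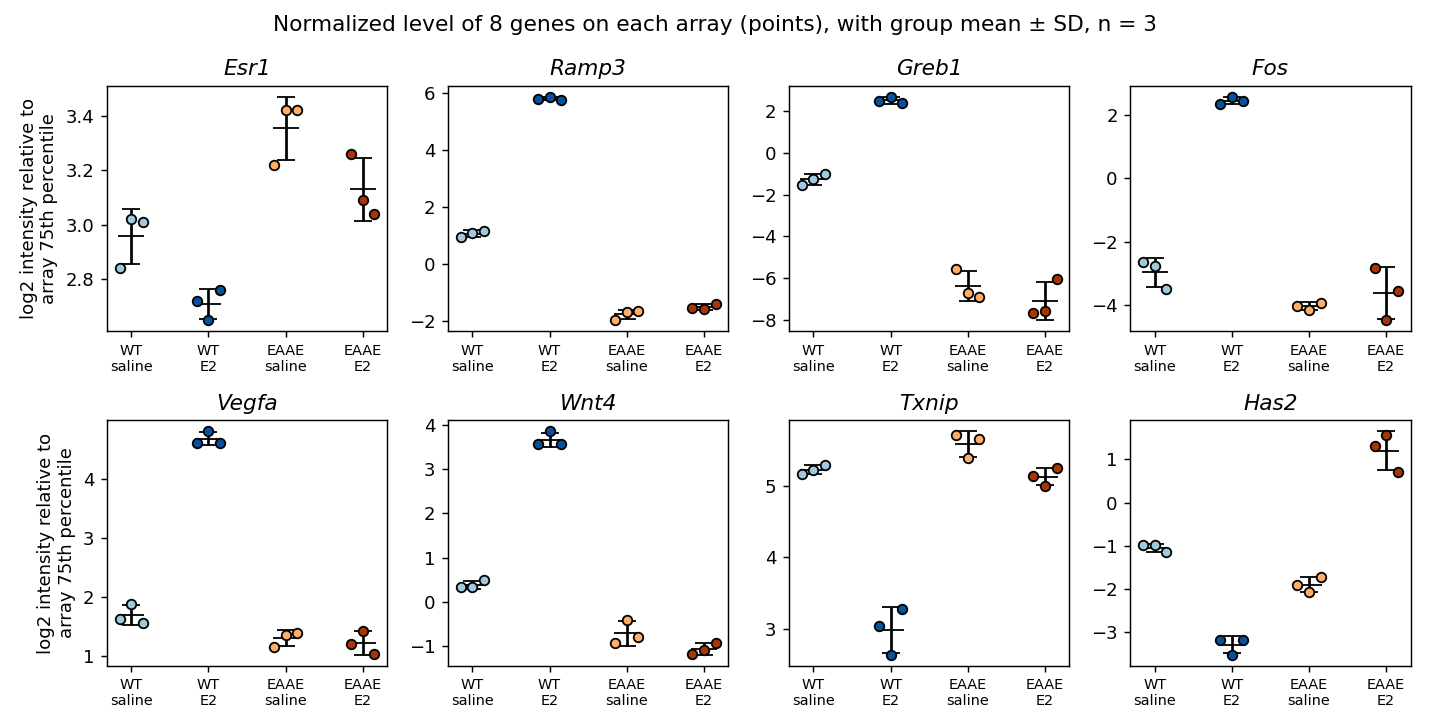
Log2 intensity of 8 genes relative to the array's 75th percentile, 1 point per array, with group means and SD (n = 3). Ramp3, Fos, Vegfa and Wnt4 separate WT E2 from the other groups, while Greb1 was not well above background in either EAAE group and Has2 moved in opposite directions in the WT and EAAE groups.

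In the WT uterus, E2 raised immediate early genes and known estrogen targets within 2 h. Fos, an AP-1 subunit, rose by log2 5.41 (SE 0.35, adjusted p = 1.31e-06, n = 3 per group), and Ramp3, an adrenomedullin receptor partner and direct receptor target, by 4.72 (SE 0.10, adjusted p = 2.88e-09). Vegfa, which opens and grows blood vessels, rose by 2.99 (SE 0.13), and Wnt4, which patterns the endometrium, by 3.29 (SE 0.14). Greb1, a coactivator of the receptor, rose by 3.78 (SE 0.44) and Igf1, the growth factor that stroma sends to epithelium, by 1.21 (SE 0.27, adjusted p = 0.00354). Falling transcripts included the prostaglandin F receptor Ptgfr (-3.97, SE 0.28), the basic helix-loop-helix repressor Msc (-3.86, SE 0.24), the redox regulator Txnip (-2.24, SE 0.15) and the hyaluronan synthase Has2 (-2.25, SE 0.20, adjusted p = 9.88e-06).

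Of 19304 genes, 3757 rose and 5773 fell in WT (49.4%), with a median size of 0.69. A change of at least 2-fold was reached by 1094 of the risen and 1666 of the fallen genes. The median of all genes was -0.148 with the 75th percentile scaling and -0.011 with the array median, which changed the split to 4539 higher and 3940 lower and the higher share from 39.4 to 53.5%. The largest rises were hair keratins: Krt85 was at least 1074.9-fold higher (adjusted p = 2.88e-09), Krt87 rose by 8.72 (SE 0.17) and Krt86 by 8.34 (SE 0.29). The latter pair were above background on 2 of 3 WT saline arrays and near-identical copies make their probes uncertain. The same holds for the kallikreins Klk1b5 (7.03) and Klk1b3 (5.79). Other large rises included Egr4 (at least 68.0-fold) and Trim15 (at least 29.7-fold), whose bounds give them no rank. The synaptic activity gene Arc (6.33, SE 0.18), the stress cytokine Gdf15 (5.97, SE 0.30), the aggrecanase Adamts4 (5.83, SE 0.23) and Has1 (5.59, SE 0.35) rose too. Falls that have bounds only, and so no rank, included the epithelial cytokine Tslp (at least 4.0-fold) and the fat cell lactate receptor Hcar1 (at least 6.8-fold). Adipocyte-restricted genes also fell on these arrays, by a median of -3.32. Groups of 3 lie fully apart for 10% of unchanged genes by chance.

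Immediate early genes, which answer growth signals without new protein synthesis, were the most shifted list (36 of 39 members higher and 0 lower, median 2.42, adjusted p = 2.65e-25). Members with large rises were Nr4a1 (3.99, SE 0.12), Egr1 (2.99, SE 0.22), Ier2 (2.97) and Cebpb (3.29, SE 0.16). Known estrogen targets followed (27 higher and 5 lower of 36, median 1.90, adjusted p = 1.08e-11). They included the mitotic checkpoint gene Mad2l1 (4.25, SE 0.15), the activin subunit Inhbb (5.25, SE 0.24) and Nrip1 (2.62), a corepressor that feeds back on the receptor. Pgr, the progesterone receptor, rose by 1.94 (SE 0.24, 4.63 on another probe), the cell cycle inhibitor Cdkn1a by 2.98 (SE 0.19) and Myc by 1.30 (SE 0.12). The cyclin Ccnd1 (-0.12, adjusted p = 0.486) and the late secretory gene Ltf (-1.28, adjusted p = 0.0854) were not called. Ribosome biogenesis rose almost as a whole (38 of 41 higher, 40 when adjusted over the list alone, median 1.12, adjusted p = 4.25e-21), with Nolc1 (1.96, SE 0.07), Bysl (1.86) and Grwd1 (1.75). These 3 lists were the only ones called with an estimated correlation (adjusted p = 0.00113, 0.00113 and 0.0198).

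Genes of protein synthesis and folding rose too, by the preset correlation. Heat shock genes rose in 15 of 19 (median 0.75, adjusted p = 6.7e-07, 0.277 with an estimated correlation), including Hsph1 (1.87) and Dnajb1 (1.43). The list of endoplasmic reticulum chaperones and the unfolded protein response had 15 higher and 1 lower of 24 (median 0.41, adjusted p = 2.37e-05, 0.19 with an estimated correlation), including Atf4 (2.31, SE 0.08), Chac1 (2.86) and Hspa5 (1.11, SE 0.10). Among tRNA synthetases and amino acid transport genes 18 of 28 were higher and 2 lower (median 0.38, adjusted p = 0.00037, 0.19 with an estimated correlation), including Slc7a5 (2.68, SE 0.16) and Aars (1.12). Over the other alternatives their adjusted p ranged from 8.02e-08 to 7.41e-06, from 4.96e-06 to 0.000331 and from 0.000189 to 0.00373. Glucocorticoid-inducible genes rose (9 higher and 3 lower of 19, median 0.46, adjusted p = 0.00586, 0.531 with an estimated correlation, 0.000414 to 0.0179 otherwise), with Errfi1 (3.66) and Sgk1 (2.28). So did vascular and hypoxia-inducible genes (10 higher and 4 lower of 26, or 10 and 5 adjusted over the list alone, median 0.21, adjusted p = 0.0191, 0.458 with an estimated correlation, 0.00325 to 0.0333 otherwise), with the vasodilator peptide Adm (2.66). Cytokines and chemokines rose (9 higher and 5 lower of 31, median 0.10, adjusted p = 0.0213, 0.635 with an estimated correlation, 0.00211 to 0.0402 otherwise). Members that rose included the cytokine Il11 (3.20) and, among the related genes that this list also holds, the feedback inhibitor Socs3 (3.79) and the prostaglandin synthase Ptges (4.01). Cholesterol and lipid synthesis rose (11 higher and 5 lower of 25, or 12 and 5 adjusted over the list alone, median 0.25, adjusted p = 0.0233, 0.635 with an estimated correlation, 0.00253 to 0.0669 otherwise). This call was lost without WT saline 3 (adjusted p = 0.0669).

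A pair of lists fell. Stromal markers lost 13 of 20 members and gained 2 (14 and 2 adjusted over the list alone, median -0.69, adjusted p = 0.035, 0.458 with an estimated correlation, 0.0175 to 0.204 otherwise). They included Hand2 (-1.17), which holds back epithelial growth, and the growth factor receptor Pdgfra (-0.74). Homeobox and Mullerian patterning genes fell in 10 of 18 and rose in 0 (median -0.55, adjusted p = 0.0422, 0.635 with an estimated correlation, 0.0253 to 0.0695 otherwise). Those lower included Hoxa9 (-1.90, SE 0.11) and Hoxa10 (-1.45, SE 0.10), which set uterine identity. The stromal call was lost with slide as a block (adjusted p = 0.0886) and without WT E2 3 (adjusted p = 0.0516). The homeobox call was lost without WT saline 2 (adjusted p = 0.0695), WT E2 2 (0.055), WT E2 3 (0.0516), EAAE saline 2 (0.0541) or EAAE saline 3 (0.0509), and with quantile scaling (0.0579).

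The remaining 23 lists were not called in WT, though single members changed. Adipocyte markers had the lowest median, -2.31 (1 higher and 11 lower of 17, 12 adjusted over the list alone, adjusted p = 0.115). Thrsp stood at -2.31 (SE 0.32), Lipe at -1.25 and Lep at least 3.4-fold lower, against Pparg at 2.60. Hedgehog genes had a median of -0.43 (2 higher and 9 lower of 15, adjusted p = 0.13, with the coreceptors Gas1 at -2.04 and Boc at -1.60, and the stromal factor Nr2f2 at -1.56). Macrophage markers had -0.57 (0 and 3 of 22, or 0 and 2 over the list alone, adjusted p = 0.144) and interferon-stimulated genes -0.41 (3 and 14 of 31, adjusted p = 0.144, with Rsad2 at -2.33). TGF-beta, activin and BMP genes had 0.04 (11 and 7 of 36, adjusted p = 0.17, with Skil at 1.82 and Bambi at -1.39). Oviduct and ciliated cell markers stood at -0.51 (1 and 8 of 14, adjusted p = 0.174) and clock genes at 0.21 (7 and 6 of 19, adjusted p = 0.184, with Nfil3 at 2.70 and Per2 at 1.34). IGF genes stood at -0.21 (1 and 6 of 15, adjusted p = 0.263) and endothelium at -0.24 (1 and 7 of 20, adjusted p = 0.263, with Cldn5 at -1.49).

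Medians and adjusted p of the others in WT were -0.09 and 0.788 for Wnt genes (6 higher and 13 lower of 37), whose receptors Fzd1 (-2.76) and Fzd7 (-1.70) fell. They were -0.06 and 0.788 for steroid receptors and cofactors (9 and 10 of 27), where the thyroid hormone receptor Thra fell by 1.61, and -0.12 and 0.522 for G1 cyclins and inhibitors (7 and 9 of 23), where Cdk6 fell by 1.09. Values were -0.23 and 0.998 for DNA replication and mitosis (3 and 3 of 36), -0.45 and 0.998 for extracellular matrix (9 and 13 of 40) and -0.15 and 0.489 for uterine epithelium (7 and 3 of 25), where the epithelial factor Elf3 rose by 2.16. Smooth muscle had -0.05 and 0.949 (1 and 3 of 20, or 1 and 0 over the list alone) and skeletal muscle 0.02 and 0.572 (2 and 2 of 14). Among blood cells, granulocytes and mast cells had -0.59 and 0.773 (1 and 1 of 18), lymphocytes -0.36 and 0.522 (0 and 0 of 19) and erythroid cells 0.33 and 0.773 (0 and 0 of 7). For ovary they were -0.11 and 0.676 (1 and 3 of 7), for mesothelium -0.61 and 0.737 (1 and 1 of 12) and for nerve and Schwann cells -0.17 and 0.982 (2 and 5 of 12). Steroid receptors (mean 0.14), G1 genes (mean 0.11), epithelium (mean 0.06) and extracellular matrix (mean 0.02, but -0.01 with quantile scaling) tested upward against a negative median. So did DNA replication (mean -0.06, but 0.08 with the array median) and smooth muscle (mean -0.04, but 0.10 with the array median), while nerve markers tested downward with a mean of 0.07.

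**Figure D2:**
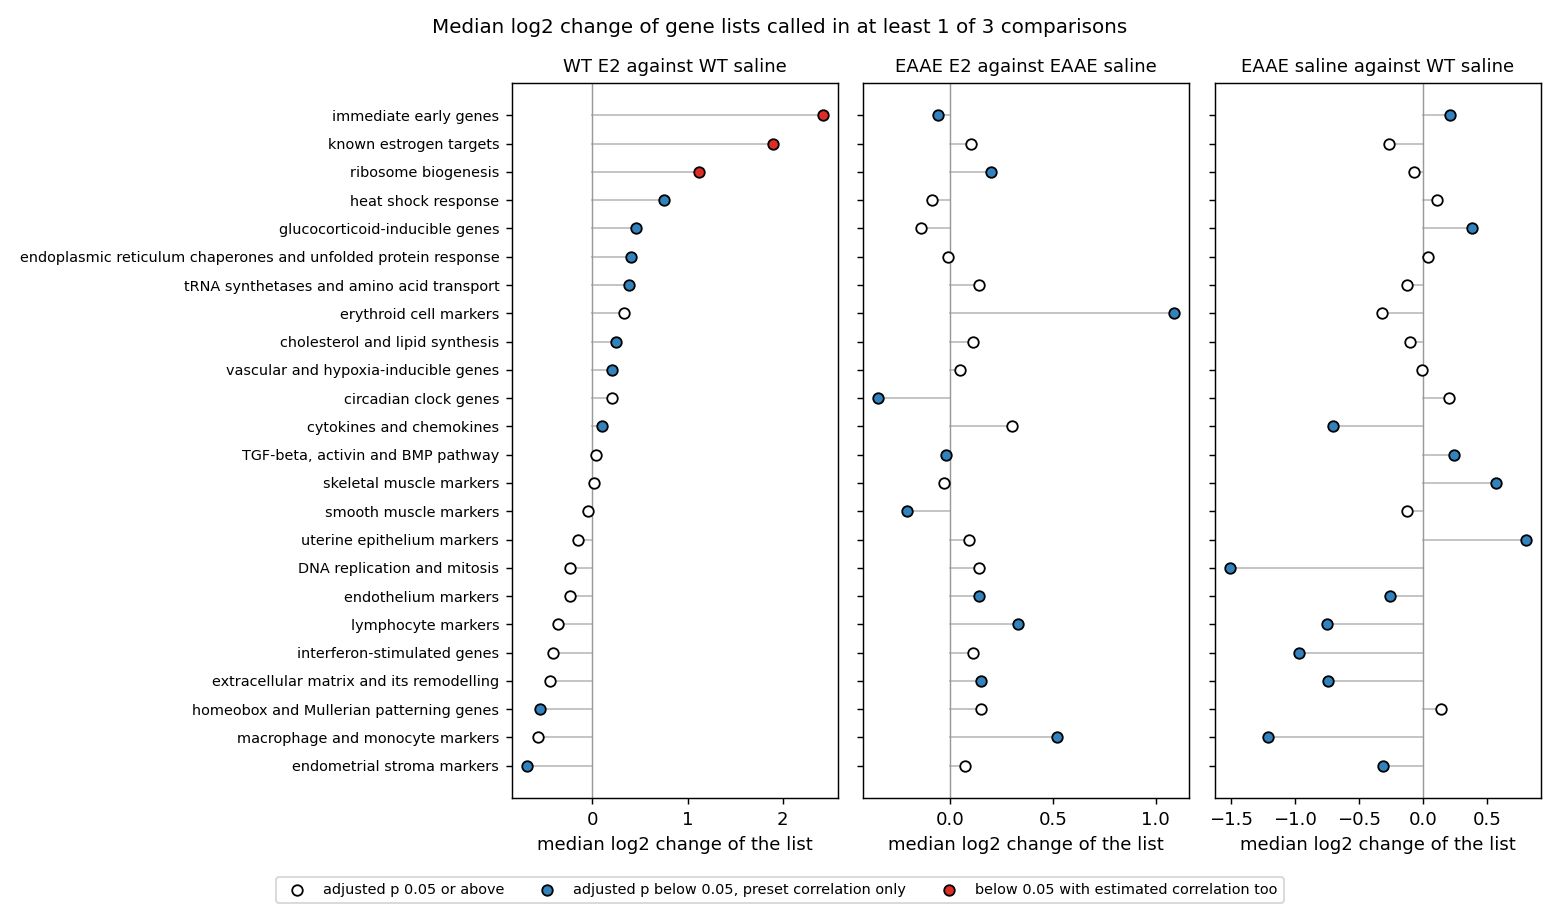
Median log2 change of gene lists called in at least 1 of the comparisons plotted, 1 point per list and comparison, with open points for adjusted p of 0.05 or more, blue for calls with the preset correlation only and red for calls that also held with an estimated correlation. Immediate early genes, known estrogen targets and ribosome biogenesis are red for E2 in WT, with medians of 2.42, 1.90 and 1.12. No list is red for E2 in EAAE or for genotype under saline.

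In the EAAE uterus, E2 changed few transcripts past the threshold. Has2, which makes the matrix sugar hyaluronan, rose by log2 3.1 (SE 0.20, adjusted p = 0.000154, 2.67 on another probe), against its fall in WT. Osr1, a mesenchymal zinc finger factor, rose by 1.54 (SE 0.08, adjusted p = 7.44e-05), the thyroid hormone activating enzyme Dio2 by 1.94 (SE 0.15, adjusted p = 0.000548) and the protease Adamts1 by 1.20 (SE 0.15, adjusted p = 0.00626). Id3, a target of BMP signals, fell by 0.96 (SE 0.09, adjusted p = 0.00165), and the clock repressor Bhlhe40, which rose by 2.08 in WT, fell by 0.87 (SE 0.09, adjusted p = 0.00268). Fos (0.42, adjusted p = 0.583), Ramp3 (0.26, adjusted p = 0.248), Vegfa (-0.08, adjusted p = 0.795) and Wnt4 (-0.35, adjusted p = 0.266) were not called. Igf1 was not called either, but stood 1.07 higher after E2 (adjusted p = 0.0859), near its rise of 1.21 in WT, with all 3 EAAE E2 arrays above the EAAE saline arrays. Its response did not differ past the threshold between the genotypes (-0.15, adjusted p = 0.781).

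Over the genome, 133 genes rose and 138 fell in EAAE (1.4%), with a median size of 0.79. Leaving out 1 array gave 37 and 25 without EAAE saline 2, 47 and 42 without EAAE saline 1, 63 and 53 without EAAE saline 3, 58 and 53 without EAAE E2 1, 43 and 39 without EAAE E2 2 and 175 and 206 without EAAE E2 3. The counts were 107 and 91 without WT saline 1, 87 and 72 without WT saline 2, 82 and 63 without WT E2 1, 102 and 91 without WT E2 2 and 91 and 63 without WT E2 3, and the EAAE arrays alone gave 5 and 2. A 2-fold change was reached by 47 and 29. With the array median the calls were 128 and 75, and the higher share moved from 49.1 to 63.1%. Further rises included Ndnf (2.07, SE 0.25), the noradrenaline transporter Slc6a2 (1.53, SE 0.17) and the hyaluronan depolymerase Cemip (1.42, SE 0.19). Falls included Nipal4 (-1.82, but -0.24 on another probe), Ccdc69 (-1.46, but -0.37 on another), the endothelin Edn2 (-1.28, SE 0.18), Sertad4 (-1.21), the deubiquitinase Usp2 (-1.13, SE 0.14) and Klf10 (-0.88, SE 0.12). All EAAE E2 arrays lay at position 4 of their slide, and with position as a linear term 12 genes rose and 12 fell. Has2 and Osr1 kept their calls under every alternative run on them, and Dio2 and Edn2 lost theirs only when position and slide were both fitted, whereas 4 of the 49 called among the named genes held under all alternatives chosen beforehand and run on them.

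The genes called in WT had mean changes near 0 in EAAE. The 3757 genes higher in WT changed by a mean of 0.931 there and of -0.003 in EAAE (SD of array means 0.017 for E2 and 0.005 for saline, exact permutation p = 0.80, 2-sided, smallest possible 0.1). The 5773 lower genes changed by -0.869 in WT and 0.007 in EAAE (SD 0.007 and 0.019, exact permutation p = 0.70). Across genes, which are not independent replicates, WT and EAAE changes had r of -0.039 and 0.033. Of the 133 genes that rose in EAAE, 40 rose and 63 fell in WT, where independent lists would share 25.9 and 39.8. Of the 138 that fell, 44 fell and 46 rose in WT, against 41.3 and 26.9.

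**Figure D3:**
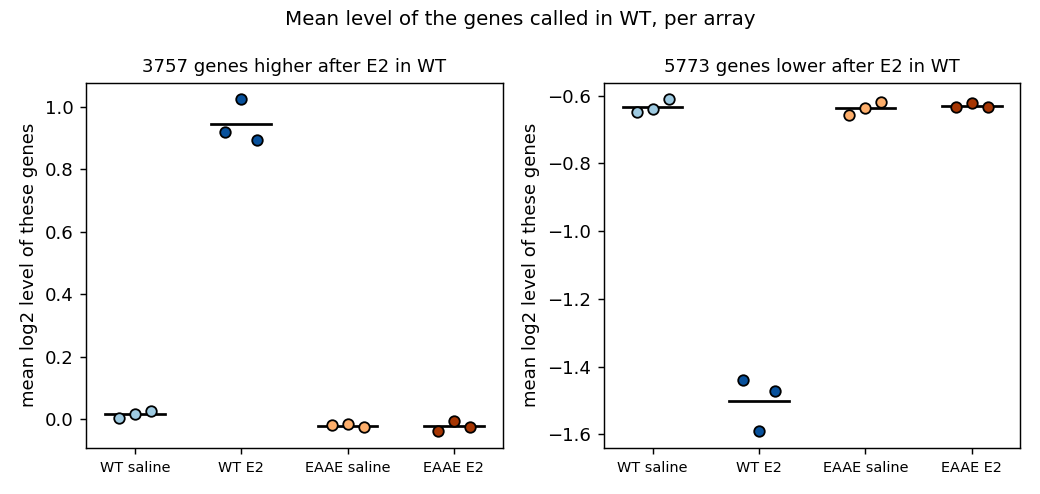
Mean log2 level per array of the 3757 genes higher and the 5773 genes lower after E2 in WT, 1 point per array, with lines at group means. WT E2 arrays lie at 0.893 to 1.024 and at -1.591 to -1.440, while the EAAE E2 arrays lie at -0.039 to -0.005 and at -0.634 to -0.621, next to the saline arrays.

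None of the 36 known estrogen targets was called in EAAE (2 higher and 0 lower adjusted over the list alone, median 0.10, adjusted p = 0.802). Markers of several cell types were higher after E2 in EAAE by the preset correlation, but none of the 10 lists called in EAAE held with an estimated correlation, whose adjusted p is given second. They were those of macrophages (median 0.52, adjusted p = 0.00255 and 0.775, 0 of 22 members called) and lymphocytes (median 0.33, adjusted p = 0.01 and 0.677, 0 of 19). Markers of endothelium (median 0.14, adjusted p = 0.0121 and 0.677, 1 of 20 higher, 2 over the list alone) and of erythroid cells (median 1.09, adjusted p = 0.0335 and 0.62, 1 of 7) were higher too. Ribosome biogenesis (median 0.20, adjusted p = 1.52e-05 and 0.416, 1 higher of 41) and extracellular matrix (median 0.15, adjusted p = 0.00696 and 0.677, 2 higher of 40, 6 over the list alone) were higher as well. Clock genes were lower (median -0.35, adjusted p = 5e-06 and 0.304, 2 of 19, 3 over the list alone), as was smooth muscle (median -0.21, adjusted p = 0.000961 and 0.677, 0 of 20, 2 over the list alone). Immediate early genes were lower against the other genes (median -0.06, adjusted p = 0.00208 and 0.373, 4 of 39, or 2 higher and 11 lower over the list alone). So were TGF-beta, activin and BMP genes (median -0.02, adjusted p = 0.0381 and 0.36, 1 higher and 3 lower of 36, or 2 and 8 over the list alone). The other 25 lists had adjusted p of 0.0697 to 0.961.

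Over the other alternatives the highest adjusted p were 0.000314 for clock genes and 0.035 for immediate early genes, which held throughout, and 0.083 for ribosome biogenesis. Without EAAE E2 1, macrophages (adjusted p = 0.715, range over alternatives 4.79e-11 to 0.715), lymphocytes (0.173), endothelium (0.425), extracellular matrix (0.425), smooth muscle (0.117) and TGF-beta genes (0.0733) lost their calls. Leaving out EAAE saline 1 ended those of endothelium (0.0754), erythroid cells (0.0614) and TGF-beta genes (0.0614). Leaving out EAAE E2 2 or EAAE E2 3 ended those of erythroid cells (0.0556 and 0.0913) and TGF-beta genes (0.0556 and 0.0953), which also lost theirs without EAAE saline 3 (0.0714). With slide as a block endothelium reached 0.0506. The lowest adjusted p over the alternatives were 0.000188 for lymphocytes, 0.00157 for endothelium, 3.15e-07 for extracellular matrix, 1.76e-08 for smooth muscle, 0.0227 for TGF-beta genes and 0.0118 for erythroid cells. Within slide 2 the macrophage median was -0.26, and within slide 1 immediate early and TGF-beta genes had means of 0.04 and 0.01 against medians of -0.17 and -0.07.

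In EAAE, hedgehog genes (median 0.01, mean 0.11) and skeletal muscle (median -0.03, mean 0.02) tested downward, as did granulocytes (median 0.16) and adipocytes (median -0.04, mean 0.01), and vascular genes (median 0.05) tested upward. The means of vascular, glucocorticoid-inducible, granulocyte and adipocyte genes lay near 0 and changed sign with the scaling.

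The responses of the genotypes were compared gene by gene as EAAE minus WT. Genes that E2 raised in WT had negative differences, among them Fos -4.98, Ramp3 -4.46, Wnt4 -3.64, Cebpb -3.82, Cdkn1a -3.26, Vegfa -3.07 and Egr1 -2.78. Differences were positive for Ptgfr (5.35), Has2 (5.34), Msc (3.82) and Txnip (1.79), which E2 lowers in WT, and for Hgf (4.05), a growth factor for epithelium. Response differences of 7245 genes passed the threshold (37.5%), 4383 of them higher and 2862 lower in EAAE, with a median size of 0.86. With the array median the split was 3103 higher and 3130 lower, 49.8% higher in place of 60.5%, as the median of all genes moved from 0.154 to 0.050. At least 2-fold differences numbered 1672 and 1197.

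The response was lower in EAAE for 2651 of the 3757 genes raised in WT (70.6%) and higher for 3959 of the 5773 lowered there (68.6%), and 630 of the genes with a response difference were not called in WT. Opposite signs of the WT change and the difference were seen for 89.3% of genes, against 75% in 20 simulations with no effect, since both use the WT arrays, and in these simulations a mean of 0.1 genes were called in both. The simulations held no E2 effect in either genotype, so they show what shared noise gives, and not what equal responses would give. Independent lists would share 557 and 1311 genes, a figure that leaves out the shared arrays. The correlation across genes was -0.93 (simulated -0.71) and the covariance -0.683 (simulated -0.053). Splitting the WT arrays would leave fewer than 2 in some groups, so part of the excess may come from the shared arrays.

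By gene lists, the response difference was negative for immediate early genes (34 of 39 lower and 1 higher, or 34 and 2 adjusted over the list alone, median -2.48, adjusted p = 6.43e-27). Known estrogen targets (25 lower and 5 higher of 36, median -1.64, adjusted p = 1.9e-11) and ribosome biogenesis (31 lower of 41, 33 over the list alone, median -0.98, adjusted p = 2.42e-17) followed. All 3 held with an estimated correlation (adjusted p = 0.000902, 0.000902 and 0.0356). With the preset correlation only, it was negative for heat shock genes (12 lower of 19, 14 over the list alone, median -0.92, adjusted p = 2.98e-07, 0.251 estimated). Endoplasmic reticulum genes (15 lower of 24, median -0.56, adjusted p = 5.84e-06, 0.18 estimated) and clock genes (8 lower and 2 higher of 19, or 8 and 3 over the list alone, median -0.33, adjusted p = 0.0113, 0.341 estimated) had negative differences too. So had tRNA synthetases and transport (9 lower and 1 higher of 28, or 12 and 2 over the list alone, median -0.19, adjusted p = 0.0113, 0.341 estimated). Glucocorticoid-inducible genes (9 lower and 5 higher of 19, median -0.75, adjusted p = 0.0137, 0.551 estimated) and vascular genes (10 lower and 1 higher of 26, median -0.17, adjusted p = 0.0193, 0.457 estimated) completed the group. Over the other alternatives run on lists none of these 6 lost its call, with highest adjusted p of 1.86e-06, 6.22e-05, 0.0156, 0.0296, 0.0295 and 0.0402.

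A pair of lists were nearer the threshold. They were TGF-beta genes (13 lower and 7 higher of 36, 14 and 7 over the list alone, median -0.08, adjusted p = 0.0422, 0.18 estimated) and cholesterol synthesis (9 lower and 3 higher of 25, 10 and 3 over the list alone, median -0.35, adjusted p = 0.0422, 0.686 estimated). Without EAAE E2 3, EAAE saline 3 or WT saline 1 the TGF-beta list stood at 0.052, 0.0517 and 0.0522 (range over alternatives 0.035 to 0.0627). The cholesterol list stood at 0.0591 without EAAE E2 2, 0.0641 without EAAE saline 2, 0.0613 without WT E2 2, 0.0563 without WT E2 3, 0.0666 without WT saline 2 and 0.102 without WT saline 3 (range 0.00738 to 0.102). A positive difference was seen for homeobox genes (9 of 18 higher, 10 over the list alone, median 0.83, adjusted p = 0.0173, 0.536 estimated, 0.00676 to 0.0332 otherwise). Macrophage markers also had a positive one (3 of 22 higher, 1 over the list alone, median 1.10, adjusted p = 0.0141, 0.789 estimated, 2.46e-05 to 0.0437 otherwise). The other 22 lists had adjusted p of 0.0579 to 0.9. Cytokines (median 0.29, mean -0.20), steroid receptors (0.02, -0.26), epithelium (0.13, -0.01) and nerve markers (0.16, -0.14) tested downward against their medians.

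Before hormone, the EAAE arrays already differed widely from the WT arrays, in a comparison partly tied to slide and position. Known estrogen targets were not called as a list (4 higher and 9 lower of 36, or 4 and 10 adjusted over the list alone, adjusted p = 0.13, 0.46 with an estimated correlation), but single ones were lower. Greb1 was at least 20-fold lower (adjusted p = 2.86e-05), Ramp3 lower by log2 2.83 (SE 0.10, adjusted p = 2.83e-07) and Wnt4 by 1.10 (SE 0.14, adjusted p = 0.000335). The secreted Wnt inhibitor Wif1 was lower by 7.42 (SE 0.69, adjusted p = 4.37e-05) and the cystine transporter Slc7a11 by 4.86 (SE 0.27). Among the largest rises was Dlk1, a Notch ligand relative of progenitor cells (6.65, SE 0.36, adjusted p = 1.6e-06). Also higher were the retinoic acid hydroxylase Cyp26a1 (3.90, SE 0.16), the imprinted growth factor Igf2 (2.01, SE 0.22) and Wnt11 (2.65, SE 0.15).

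Under saline 2636 genes were higher and 3058 lower in EAAE (29.5%), with a median size of 0.67, and 697 and 953 of them by at least 2-fold. With slide as a block the counts were 1643 and 1975, and with slide and position both fitted 218 and 198, where 36 of 152 named genes kept their call. Other large rises were Pde6h (5.88, SE 0.31), the cornea keratin Krt12 (5.52), Esrrb (at least 11.3-fold), a nuclear receptor of stem cells, Sox2ot (at least 7.2-fold) and the cardiac troponin Tnnt2 (4.01, SE 0.23). Other large falls were Clvs2 (at least 13.8-fold), the junction gene Trdn (at least 13.6-fold), Gjb6 (at least 12.9-fold), Cxcl15 (-5.69), Asb4 (-5.29) and the progesterone-metabolizing enzyme Akr1c14 (-4.71). Foxa2, the gland factor, differed by -2.39 (SE 0.29) and the cilia factor Foxj1 by -3.79 (SE 0.34), while Pgr (-0.57, adjusted p = 0.105), Cdkn1a (-0.49, adjusted p = 0.0732) and Txnip (0.36) were not called.

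DNA replication and mitosis genes were lower in 31 of 36 and higher in 0 (33 over the list alone, median -1.51, adjusted p = 1.64e-18, 0.425 with an estimated correlation). They included Cdc20 (-2.06, SE 0.12), Kif20a (-2.64), Plk1 (-1.46) and Mcm5 (-1.01), but the G1 cyclin Ccnd2 was higher (1.87, SE 0.11). G1 cyclins and inhibitors as a list were not called (4 higher and 9 lower of 23, or 4 and 12 over the list alone, median -0.47, adjusted p = 0.136). Interferon-stimulated genes were lower in 24 of 31 (27 over the list alone, median -0.97, adjusted p = 8.02e-12, 0.46 estimated), with Isg15 (-1.81, SE 0.16), Oas1a (-1.64) and Bst2 (-1.48). Extracellular matrix was lower in 19 and higher in 2 of 40 (median -0.74, adjusted p = 8.67e-05, 0.46 estimated), with the matricellular genes Tnc (-2.24, SE 0.22) and Thbs2 (-2.36). Under the other alternatives run on lists the adjusted p of the replication, interferon and matrix lists was at most 9.84e-16, 0.000207 and 0.00321.

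Epithelial markers were higher (20 of 25, 1 lower, median 0.80, adjusted p = 7.97e-09, 0.425 with an estimated correlation and at most 5.28e-07 otherwise). Among them were the secreted inhibitor Wfdc2 (1.5, SE 0.15), the epithelial factor Grhl2 (1.12) and the adhesion gene Cdh1 (0.81). Stroma was lower (6 of 20, 1 higher, or 8 and 1 over the list alone, median -0.31, adjusted p = 0.0304, 0.46 with an estimated correlation), with the collagen organizer Lum (-1.39). Endothelium was lower (6 of 20, 1 higher, median -0.26, adjusted p = 0.0211, 0.538 estimated), with Plvap (-1.41) against Sox17 (1.23). Macrophage markers were lower (13 of 22, 1 higher, or 16 and 2 over the list alone, median -1.21, adjusted p = 0.00111, 0.638 estimated), with Ms4a7 (-2.35) against the scavenger receptor Cd163 (2.07). Lymphocyte markers were lower (8 of 19, median -0.75, adjusted p = 0.00512, 0.46 estimated), with Gzmb (-2.44, SE 0.32). Cytokines and chemokines were lower in 12 and higher in 3 of 31 (15 and 3 over the list alone, median -0.70, adjusted p = 0.0117, 0.56 estimated), with Ccl4 (-1.94) and Cxcl14 (-2.52). With slide and position both fitted, macrophages and cytokines reached 0.435 and lymphocytes 0.202, from lowest values of 1.1e-05, 0.00179 and 0.00157 over the alternatives. With slide as a block stroma and endothelium both stood at 0.0824. Stroma was also lost without EAAE saline 1 (0.0729) or WT saline 2 (0.0657), and endothelium without EAAE saline 1 (0.0527), with ranges of 0.0119 to 0.326 and 0.0108 to 0.0824.

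Glucocorticoid-inducible genes were higher under saline in EAAE (9 of 19, 1 lower, or 9 and 3 over the list alone, median 0.38, adjusted p = 0.00111, 0.46 estimated, at most 0.00603 otherwise). They included the chaperone Fkbp5 (2.10), Mt2 (1.49, SE 0.10) and Mt1 (1.22). Immediate early genes were higher (11 of 39, 4 lower, or 12 and 4 over the list alone, median 0.21, adjusted p = 0.0244, 0.46 estimated), with Maff (1.85). This call was lost without WT saline 3 (0.0523, range over alternatives 0.0028 to 0.0523). Skeletal muscle markers were higher (7 of 14, 2 lower, median 0.57, adjusted p = 0.0311, 0.536 estimated), with Tnnc2 (4.29, SE 0.56) and Tnnt1 (2.46). Leaving out EAAE saline 1 (0.0527) or WT saline 2 (0.0508) ended it (range 0.00597 to 0.0527). TGF-beta, activin and BMP genes were higher (12 of 36, 4 lower, or 13 and 6 over the list alone, median 0.24, adjusted p = 0.0394, 0.425 estimated), with the activin trap Fst (1.97) and Id2 (1.27). That call was lost without EAAE E2 1 (0.0569), EAAE saline 1 (0.0527), EAAE saline 3 (0.0551) or WT saline 1 (0.0519), range 0.0329 to 0.211. The other 22 lists had adjusted p of 0.068 to 0.945, with known estrogen targets at a median of -0.27. Vascular (median -0.01, mean -0.05) and IGF genes (-0.18, -0.02), and steroid receptors (0.11, -0.04) and oviduct markers (0.14, -0.29) with their negative means, tested upward, and the smooth muscle mean changed sign with quantile scaling (0.02).

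After E2, 6372 genes were higher and 4779 lower in EAAE than in WT (57.8%), with a median size of 0.80, and 2485 and 1751 by at least 2-fold. The higher share of 57.1% became 50.4% with the array median. Within slides 1, 2 and 3 the called higher genes had median differences of 0.74, 0.79 and 0.91, and the lower genes of -0.72, -0.78 and -0.85. For E2 in WT the medians within slides 1 and 3 were 0.65 and 0.74 for risen and -0.64 and -0.78 for fallen genes. For E2 in EAAE, slides 1 and 2 gave 0.84 and 0.90 for risen and -0.74 and -0.78 for fallen genes, and for genotype under saline slide 1 gave 0.72 and -0.66. These genes and the lists below were called on the same arrays, so within-slide agreement was largely given by their choice. Most of these within-slide comparisons set 1 array against 1. Of the lists called for E2 in WT, 11 of 12 kept their direction within slide 1 and 12 within slide 3, judged by the mean, the exception being cholesterol synthesis (mean -0.03, median 0.16). By the median, vascular genes (-0.03) and cytokines (-0.02) also turned in slide 1. For E2 in EAAE 8 of 10 kept it in slide 1 and 9 of 10 in slide 2 by the mean, while the medians of erythroid markers in slide 1 (-0.13) and of extracellular matrix in slide 2 (-0.08) turned too. Under saline all 13 kept it in slide 1.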

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

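The results here share 1 reason for a closer look, a difference between the genotypes in the response to E2 that passed limma's test of the difference itself. No test in this part was chosen after its result was seen, apart from the fits with position on the slide.

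The response was higher in EAAE than in WT for 4383 genes and lower for 2862. The largest negative differences, where E2 gave a weaker rise or a fall in EAAE, were those of Krt85 -10.48, Krt87 -8.44, Krt86 -8.36, Egr4 -6.72, Klk1b5 -6.60, Csrnp3 -6.51 (but -1.35 on another probe), Trim15 -6.34, Arc -6.26, Adamts4 -6.20, Klk1b3 -5.66, Gdf15 -5.64 and the water channel Aqp5 -5.32. Values for genes not well above background in a group are fitted and give no measured fold. Of the genes fixed for every comparison, these differed in the same direction: Fos -4.98, Greb1 -4.48, Ramp3 -4.46, Cebpb -3.82, Wnt4 -3.64, Cdkn1a -3.26, Vegfa -3.07, Egr1 -2.78, Pgr -1.55, Hspa5 -1.16 and Myc -1.01. Of the same genes, Igf1 (-0.15, adjusted p = 0.781, range over alternatives 0.219 to 0.995), Ltf (0.53, adjusted p = 0.632, range 0.346 to 0.998) and Ccnd1 (-0.12, adjusted p = 0.643, range 0.307 to 0.969) showed no difference past the threshold.

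Positive differences were led by Ptgfr 5.35 and Has2 5.34, followed by Saxo1 4.40, Mup1 4.15, the estrogen hydroxylase Cyp1b1 4.15, Slc13a1 4.12, Hcar1 4.07, Hgf 4.05, Mup4 3.84, the interleukin antagonist Il1rn 3.83, Msc 3.82, the Wnt receptor ligand Ndp 3.77 and Txnip 1.79. Hcar1 is a gene of fat cells, and adipocyte-restricted genes also fell in WT E2, by a median of -3.32. The call of Mup1 was lost with slide and position both fitted (adjusted p = 0.0508, range over alternatives 0.00913 to 0.0508). That of Slc13a1 (adjusted p = 0.0233, range over alternatives 0.00941 to 0.0544) was lost without WT saline 2 (0.0535), WT E2 1 (0.0511), WT E2 3 (0.0544), EAAE saline 2 (0.0528), EAAE saline 3 (0.054) or EAAE E2 2 (0.0504). The call of Il1rn (adjusted p = 0.0429, range 0.00253 to 0.105) was lost without WT saline 1 (0.094), WT saline 2 (0.0605), WT saline 3 (0.0594), WT E2 1 (0.0609), WT E2 2 (0.0681), WT E2 3 (0.089), EAAE saline 1 (0.0779), EAAE saline 2 (0.0656), EAAE saline 3 (0.0751) or EAAE E2 3 (0.0687).

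By gene list, the mean response difference was -2.63 for immediate early genes, -1.77 for known estrogen targets, -0.93 for ribosome biogenesis, -0.84 for heat shock genes, -0.78 for glucocorticoid-inducible genes, -0.68 for endoplasmic reticulum chaperones, -0.58 for clock genes and -0.53 for vascular genes. It was -0.35 for tRNA synthetases and transport, -0.26 for TGF-beta, activin and BMP genes, -0.21 for cholesterol synthesis, 0.67 for homeobox genes and 1.11 for macrophage markers. Only the first 3 were called with an estimated correlation.

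Of 100 splits of the arrays, 1 gave as many genes with a response difference as the real split, which was the real split itself (7245). This argues against chance for the treatment labels of both genotypes taken jointly, but not for those of each genotype alone. The highest other split gave 6922 and kept the WT groups whole, so the count rests mainly on the WT arrays and says little about the grouping of the EAAE arrays. The biological explanation that the design offers, the loss of DNA binding by the receptor, was not tested apart from other differences between the strains. Position on the slide cannot be separated from EAAE E2, since all arrays of this group lay at a position that no other group used. With position as a linear term 3996 genes were higher and 2716 lower, and with slide fitted as well 3537 and 2360.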

How the results depend on the processing

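The fits with position on the slide, alone or with slide as a block, were chosen after the data were seen. None of the 656 results for named genes or of the 48 for called gene lists reversed under the alternatives run on them. A filter on all 12 arrays removed some of the named genes. A list counted as reversed only where its opposite direction passed the threshold, so smaller turns in sign are not excluded. The cause of the changes below was not tested, except that fewer arrays, lost degrees of freedom or a stricter threshold lower counts by construction. Counts are given as genes higher and lower. At a 2-fold threshold they were 1094 and 1666 for E2 in WT, 47 and 29 for E2 in EAAE, 1672 and 1197 for the response difference, 697 and 953 for genotype under saline and 2485 and 1751 for genotype after E2. The EAAE response moved most: 77 and 52 genes without a filter on dim probes, 128 and 75 with the array median, 76 and 73 with slide as a block, 5 and 2 with only its own arrays (2137 at an unadjusted p under 0.05), 12 and 12 with position, 4 and 3 with slide and position, and 216 lower with all probes tested. Leaving out 1 array gave 37 to 175 higher and 25 to 206 lower: 37 and 25 without EAAE saline 2, 47 and 42 without EAAE saline 1, 63 and 53 without EAAE saline 3, 58 and 53 without EAAE E2 1, 43 and 39 without EAAE E2 2, 175 and 206 without EAAE E2 3, 107 and 91 without WT saline 1, 87 and 72 without WT saline 2, 82 and 63 without WT E2 1, 102 and 91 without WT E2 2 and 91 and 63 without WT E2 3. Genotype under saline gave 1643 and 1975 genes with slide as a block (3389 of them among the genes named by the comparison without it), 1481 and 1506 with position and 218 and 198 with slide and position, and genotype after E2 gave 4160 and 3149 with position and 2862 and 2335 with slide and position. E2 in WT gave 3731 lower genes with slide and position. The mean EAAE response of the genes higher in WT was 0.032 with the array median (exact permutation p = 0.6), and that of the lower genes 0.033 (exact p = 0.5), or 0.022 with normexp (exact p = 0.2).

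Of the gene lists, an estimated correlation left 3 higher and 0 lower for E2 in WT, 0 and 0 for E2 in EAAE, 0 and 3 for the response difference and 0 and 0 for genotype under saline. Lists lower in WT numbered 1 with quantile scaling, 1 with slide as a block, 1 with slide and position and 4 with the replicate block, and 0 to 3 with 1 array left out (0 without WT E2 3, 1 without EAAE saline 2 or EAAE saline 3). Without EAAE E2 1, 2 lists were higher and 2 lower for E2 in EAAE (2 to 7 and 2 to 5 over all arrays). For the response difference 5 were higher with quantile scaling, 4 with slide and position, 4 without WT E2 1, 5 without WT E2 2 and 6 without EAAE E2 2 (2 to 6). Under saline 3 were higher without EAAE saline 1 (3 to 6) and 4 lower with slide and position.

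Esr1 in WT was not called with normexp (-0.242, adjusted p = 0.0534), the array median (-0.109, 0.427), no filter (-0.246, 0.0864), slide as a block (-0.237, 0.104), position (-0.271, 0.0683) or slide and position (-0.281, 0.183), and ranged from -0.305 to -0.213 with 1 array left out. Its genotype difference under saline was not called with slide as a block (0.413, adjusted p = 0.0521), position (0.347, 0.106) or slide and position (0.326, 0.509).

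The replicate numbers showed no sign of pairing the mice. Deviations of same-numbered arrays correlated with r of -0.281 to 0.193 (n = 3 per group), and those of different-numbered arrays with r of -0.343 to 0.353. With 3 arrays per group this does not exclude a pairing. With the replicate block the counts were 3660 and 5697 for E2 in WT, 79 and 65 for E2 in EAAE, 4308 and 2768 for the response difference, 2554 and 2948 under saline and 6331 and 4719 after E2, Esr1 in WT stood at -0.246 (adjusted p = 0.0775), and of 48 called lists 1 lost its call, TGF-beta genes in EAAE (adjusted p = 0.0594). Of 656 named results, 24 lost and 10 gained a call with this block. Signal over background limits the dim genes, which have bounds only.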

Other observations

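The tests of estradiol lowering adipocyte genes, of a slide difference and of a residual receptor response were chosen only after the results were seen, as were the fits with position on the slide.

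Under saline, pathways that pattern the uterus carried single large differences between the genotypes although their lists were not called. In the Wnt pathway the secreted inhibitors Wif1 (-7.42) and Frzb (-2.31) were lower in EAAE and the ligand Wnt11 (2.65) was higher, and the hedgehog effector Gli1 (-1.45) and the homeobox gene Msx2 (-2.72) were lower. The glucose transporter Slc2a1 (1.14), the stress genes Gadd45b (1.44) and Hspa1a (1.35), the kinase Sik1 (1.37) and Cebpd (1.18) were higher. Chemokine Cxcl16 (-1.68), the antiviral regulator Rtp4 (-1.38), the matrix gene Mfap4 (-1.40) and the protease Mmp11 (-1.12) were lower. Not all of these calls held under the alternatives, where the highest adjusted p was 0.289 for Gli1 and 0.0541 for Frzb. It was 0.0655 for Gadd45b, 0.0619 for Hspa1a, 0.0508 for Cebpd and 0.0699 for Cxcl16. Of 152 named genes called under saline, 36 kept their call with slide and position both fitted.

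After E2 in WT, further single genes rose: the phosphatase Dusp1 by 2.59, Ppp1r15a by 2.45, Gadd45a by 1.91, Gadd45g by 4.55, Twist2 by 2.90 and the collagen hydroxylase P4ha2 by 2.39. Single genes that fell were the apelin receptor Aplnr by 1.99, the Wnt inhibitor Dkk2 by 1.77, the membrane estrogen receptor Gper1 by 1.55 and Cd14 by 1.37. The growth factor clearance receptor Igf2r (-0.81) and the binding protein Igfbp5 (-0.80) fell too, while Igf1 rose by 1.21.

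Genes of fat cells differed between mice. The mean of Adipoq, Plin1, Cfd, Cidec, Retn and Lep ranged from -3.34 to 2.91 over the arrays, with group means of 1.17 in WT saline, -2.11 in WT E2, 1.70 in EAAE saline and 1.56 in EAAE E2. All WT E2 arrays lay below all WT saline arrays (exact permutation p = 0.10, the smallest that 3 against 3 allow). Fat carried along with some uteri fits these values, since mice of the same group differed by up to 3.09. Lower expression within fat cells may still contribute and stays open: the genes fell by nearly the same amount, with an SD of 0.22 around a median of -3.32, where a change in regulation was predicted to spread them by more than 1.

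The 271 genes called for E2 in EAAE have no settled source. The median change in the direction of the call was 0.79 without and 0.81 with slide as a block. This cannot decide on a difference between slides. The groups were spread over slides, so such a difference widens the spread within groups, and the calls favour genes with little of it. Within slides 1 and 2 the risen genes had medians of 0.84 and 0.90 and the fallen genes of -0.74 and -0.78, and 100% kept their sign, on the arrays that also gave the calls. With the block 115 stayed called in the same direction, while the median SE of the 271 went from 0.13 to 0.14 and the residual degrees of freedom fell from 8 to 6. A trend along positions 1 to 3 of the WT arrays had the sign of the EAAE change for 43.9% of these genes (119), which argues against such a trend continued to position 4, but an effect of position 4 itself cannot be separated from EAAE E2. With position as a linear term 12 genes rose and 12 fell, 22 of them among the 271, and with slide as well 4 rose and 3 fell. A weak remainder of the WT response is argued against as the main source of the 271 genes, since 42.8% (116) changed in the same direction in WT. For a smaller part of them this share cannot decide. Of the genes that rose, 40 were called higher and 63 lower in WT, against 25.9 and 39.8 for independent lists. Of those that fell, 44 were called lower and 46 higher, against 41.3 and 26.9. For single genes such a remainder is not excluded. An effect of E2 that does not use direct DNA binding is a candidate explanation that was not tested. A smaller share of smooth muscle was considered for the cell marker shifts in EAAE, but its test was dropped after the smooth muscle median of -0.21 was seen (adjusted p = 0.000961, 0.677 with an estimated correlation, 0.117 without EAAE E2 1, range over alternatives 1.76e-08 to 0.117), so it stays open.

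Genes close to Esr1 could differ between the genotypes through a segment of the other parent strain carried with the altered allele. Within 20 Mb of Esr1, 11 of 120 genes (9.2%) differed at least 2-fold under saline, against 1625 of 19044 elsewhere (8.5%), an odds ratio of 1.08 (95% confidence interval 0.52 to 2.02, Fisher's exact p = 0.743). The interval holds values above and below 1, so the segment stays open. Of the 11, those nearest to Esr1, named here for their place, lay between 4505441 and 5932352. They were Armt1 (2.28, SE 0.15), Rgs17 (-1.67, SE 0.18), AK076350 (-2.26) and AK036268 (-2.11). The latter pair had EAAE saline means of -6.65 and -6.79, below any probe well above background. Narrower distances were not tested.

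Other splits of the 6 arrays of each comparison between groups were too few, at 10, for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real and the highest other counts were 9530 and 0 for E2 in WT, 271 and 31 for E2 in EAAE, 5694 and 1 for genotype under saline and 11151 and 0 for genotype after E2. The split with 31 genes put the 3 arrays of slide 2 together.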
